A study of Homo sapiens with 4 samples.

How the data were processed

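Ribosome footprints were measured in 4 human leukemia cell lines, K562, THP-1, MOLM13 and HL60, with 1 library per line. Per the labels' protocols, cells were lysed in a buffer with cycloheximide, footprints were prepared with an ARTseq kit, ribosomal RNA was depleted with Ribo-Zero, and the libraries were sequenced on an Illumina HiSeq X instrument. Per the submitters' processing notes, reads were processed with Trim Galore 0.6.6, Bowtie2 2.4.2, STAR 2.7.8a and StringTie 2.1.5 on the build hg38. Per the file headers, StringTie was run on read 1 against GENCODE release 37 with no search for new transcripts and no strand option. The deposited values are TPM, FPKM and mean per-base coverage for each transcript and coverage for each exon, per the file headers. The deposited TPM of each library sums to 1000000 over transcripts, as tested on the values. Read counts were not used here. Aligned bases were taken as the authors' coverage times transcript length, and the modal value on single-exon transcripts was 29 bases. Division of aligned bases by that length gives the footprint equivalents, and the Poisson intervals derived from them cover counting error only.

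The files hold 60651 genes, 234485 transcripts and 1460406 exons. Gene types came from GENCODE release 29 on the same build for 58405 genes, and 82 of the other 2246 were classed from RefSeq by symbol, which left 2164 not classified. This gave 19899 nuclear protein-coding genes, 13 mitochondrial ones and 14841 lncRNA genes, of which 9181 share no exon with another gene on either strand. For 12536 genes the files give no name. Coding regions came from GENCODE release 29 for the 78889 of 99026 coding transcripts with the same exons in the files. Work was done with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pyarrow 21.0.0 and Matplotlib 3.10.9.

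Transcript TPM was summed per gene and scaled per library by the median ratio to the geometric mean over 3751 genes with a TPM of at least 10 in all 4 libraries. The scaling factors were 0.837 for K562, 1.01 for THP-1, 1.12 for the library labelled MOLM13 and 1.05 for HL60. A gene is called high in a line when its log2(scaled TPM + 1) is at least 2 above the highest of the other 3 lines, with at least 600 aligned bases in that line. It is called low when it is at least 2 below the lowest of the other 3, with at least 600 aligned bases in each of them. The same distance was used for the 6 pairs of libraries.

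For 29 gene lists, members with a scaled TPM of at least 1 in any line were compared as the median log2 difference between a line and the mean of the other 3. The percentile of this median was taken among 10000 random lists of the same size, matched on expression in 20 bins, with seed 7, and a list stands apart below percentile 2.5 or above 97.5. The lists were globins, other erythroid genes, heme synthesis, megakaryocyte and platelet genes, primary and late neutrophil granules, monocyte and macrophage genes, MHC class I and class II, interferon-stimulated genes, HOXA genes and partners, stem and progenitor genes, T and NK cell genes, B cell genes, and epithelial and fibroblast genes. They also held cytosolic ribosomal proteins, translation factors, the integrated stress response, the cell cycle, glycolysis, mitochondrially encoded proteins, cholesterol synthesis, cancer-testis genes, loci altered in leukemia lines, histones, small structural RNAs, and 3 lists of lncRNA genes. Small structural RNAs were given values and no percentile. Random lists were drawn from lncRNA genes for the 3 lists of lncRNA genes and from protein-coding genes for the others. The design, the lists and their members, the rule for named genes and the first alternatives were fixed before the data were examined.

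Named genes are, for each line, the 5 high and 5 low protein-coding genes and the 3 high lncRNA genes with the largest distance to the nearest other line. They also include the 10 lncRNA genes without exon overlap that have the highest minimum over the 4 lines. From each list they include up to 4 members with the largest distance and the members against its median by over 1 log2 unit. Genes chosen later are named as such. Levels of Y-linked genes are not given, and some genes that the rule names are not reported here.

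Alternatives fixed in advance were deposited TPM without further scaling, TPM rescaled over nuclear protein-coding genes, normalized aligned bases not divided by length, pseudocounts of 0.1 and 5, log2 differences of 1 and 3, and other minimums of aligned bases, TPM and coding coverage. Further ones were coverage summed over genes, unmatched random lists and lncRNA genes without exon overlap. Leaving out genes listed at 0 and leaving out the library labelled MOLM13 were added after the values were seen. Over 3382 protein-coding genes, the median log2 difference between a line and the other 3 was -0.35, 0.02, 0.23 and 0.09 in K562, THP-1, the library labelled MOLM13 and HL60 with deposited TPM. It was 0.23, -0.23, 0.17 and -0.19 with rescaled TPM, and -0.01, -0.00, -0.08 and 0.13 with aligned bases. The code of the rules was tested on simulated data, which for single genes held counting error alone, so the result gives no error rate for the real calls: of 200 genes changed by 8-fold or 16-fold in either direction, all above the 4-fold rule, 100% were recovered, and 0 of 7913 unchanged genes were called. Of 100 lists shifted by 1 log2 unit, 98 lay outside the percentiles, as did 14 of 400 percentiles of lists with no shift. Members of these simulated lists were drawn at random and varied independently, so the result gives no error rate for real lists whose members vary together.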

Results

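Ribosome-protected RNA fragments were sequenced from 4 human leukemia cell lines, with 1 library per line and no replicates. The series concerns long non-coding RNAs (lncRNAs) that have a second function as templates for translation, and the protected fragments measure which genes carried footprint signal in each line. Protection by something other than a translating ribosome was not told apart, and small RNAs that are not translated also held signal. K562 was established from a chronic myeloid leukemia in blast crisis and has erythroid features. THP-1 and MOLM13 were established from acute monocytic leukemias with a KMT2A rearrangement, and MOLM13 also carries an internal tandem duplication of FLT3. HL60 was established from an acute promyelocytic-like leukemia and carries an amplified MYC locus. Because no line had a second library, a difference between lines has no replicate check, no p-value is given, and a gene is called high or low by a fixed rule of size. The deposited file of the library labelled MOLM13 carries another name than its label, and no reference profile of that line was used here, so this label could not be checked and every value of this library depends on it.

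Aligned depth was 473 megabases in K562, 678 in THP-1, 344 in the library labelled MOLM13 and 973 in HL60. At the modal fragment length of 29 nucleotides this corresponds to 16.3, 23.4, 11.9 and 33.6 footprint equivalents in units of 1000000. A gene at the minimum of 600 aligned bases has 20.7 such equivalents, for which a 95% Poisson interval runs from 61.7% to 153% of the value, counting error only. Genes listed above 0 numbered 15308 in K562, 18714 in THP-1, 15747 in the library labelled MOLM13 and 19083 in HL60. Protein-coding genes with a scaled TPM of at least 1 numbered 8969, 9819, 9523 and 9060 in the same order.

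Most of the signal lay on protein-coding genes. Nuclear protein-coding genes held 75.8% of aligned bases in K562, 84.7% in THP-1, 83.3% in the library labelled MOLM13 and 87.3% in HL60. Mitochondrial ribosomal RNA held 12.6%, 9.38%, 10.1% and 6.85%, and lncRNA genes held 1.46%, 1.18%, 1.18% and 0.828%. TPM, which divides by transcript length, gave small RNAs more weight: nuclear protein-coding genes held 37.8% of deposited TPM in K562, 58.4% in THP-1, 53.1% in the library labelled MOLM13 and 59.4% in HL60. Small nuclear RNAs, components of the spliceosome, held 24.8% of deposited TPM in K562 and 11.1%, 15.2% and 11.6% in the other 3. Within these shares RNU1-67P, a copy of the U1 spliceosomal RNA, held 15.0% in K562. It held 0.788% in THP-1, 4.79% in the library labelled MOLM13 and 0.475% in HL60. The higher share of the class in K562 therefore rests on that copy. Small nucleolar RNAs held 13.3% in HL60 and 6.26%, 5.08% and 6.02% in K562, THP-1 and the library labelled MOLM13. Within protein-coding genes, coverage of 3′ untranslated exons was a median of 0.182 of coding coverage in K562, 0.213 in THP-1, 0.180 in the library labelled MOLM13 and 0.251 in HL60, over 534 to 824 genes. The 3′ untranslated value lay below the coding value in 91.0%, 91.8%, 91.8% and 90.2% of these genes. Coverage of 5′ untranslated exons, a measure added after the data were examined, was a median of 0.462, 0.910, 0.378 and 0.737 of coding coverage over 1341, 1764, 1416 and 1879 genes. The ratio of summed coverage gave 3′ untranslated values of 0.322 in K562 and 0.314 in the library labelled MOLM13, over 1.5 times the medians.

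**Figure D1:**
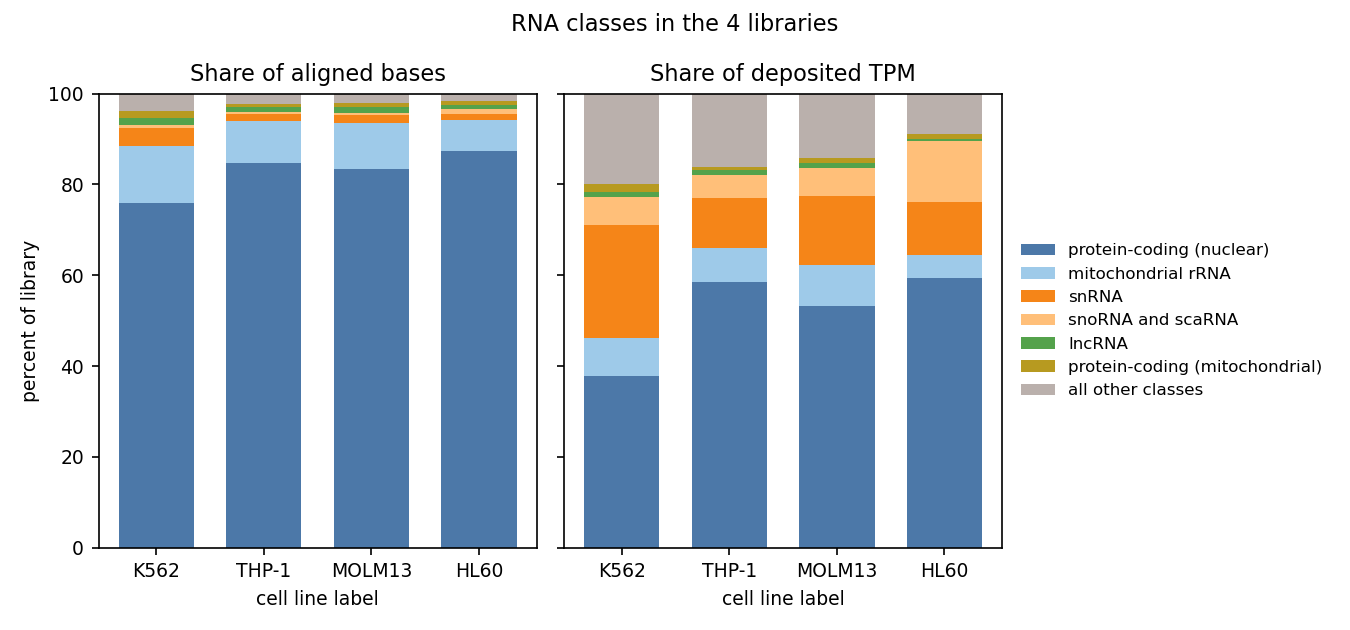
Share of aligned bases (left) and of deposited TPM (right), in percent, held by each RNA class in the 4 libraries. Nuclear protein-coding genes hold 75.8% to 87.3% of bases and 37.8% to 59.4% of TPM.

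THP-1 and HL60 were the most alike pair and K562 and the library labelled MOLM13 the next. Across 19912 protein-coding genes, Pearson's r of log2(scaled TPM + 1) was 0.908 for THP-1 and HL60 (Spearman's rho 0.882) and 0.880 for K562 and the library labelled MOLM13 (rho 0.833). It was 0.858 for the library labelled MOLM13 and HL60 (rho 0.830), 0.853 for THP-1 and the library labelled MOLM13 (rho 0.826), 0.832 for K562 and HL60 (rho 0.788) and 0.827 for K562 and THP-1 (rho 0.789). Over the 6879 genes with a scaled TPM of at least 1 in all 4 lines the order of the first 2 pairs turned, with r of 0.879 for THP-1 and HL60 and 0.889 for K562 and the library labelled MOLM13. These are correlations across genes, which are not independent replicates. THP-1 and HL60 also had the greater depth, at 678 and 973 aligned megabases against 473 in K562 and 344 in the library labelled MOLM13. Likeness of the lines therefore cannot be told apart from likeness of the libraries. The number of protein-coding genes at least 4-fold apart was 1302 for THP-1 and HL60 (899 higher in THP-1, 403 higher in HL60) and 1719 for K562 and the library labelled MOLM13 (626 and 1093). It was 2114 for THP-1 and the library labelled MOLM13 (1254 and 860), 2134 for the library labelled MOLM13 and HL60 (1205 and 929), 2310 for K562 and HL60 (1042 and 1268) and 2374 for K562 and THP-1 (756 and 1618). Leaving out genes listed at 0 in either line reduced these counts to 771, 402, 985, 1112, 984 and 933.

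Globins and red cell genes were high in K562, and genes of myeloid cells were low or listed at 0. HBE1, the embryonic epsilon globin gene on chromosome 11 (5268345 to 5505652, minus strand, hg38), reached a scaled TPM of 10580 in K562 (95% Poisson interval 10514 to 10646), 949.7-fold above the 11.1 of the library labelled MOLM13, and was listed at 0 in THP-1 and HL60. HBZ, the embryonic zeta globin gene on chromosome 16 (142728 to 154503), was at 3623 and HBG1, a fetal gamma globin gene with the near-identical copy HBG2, at 404, and both were listed at 0 in the other 3 lines. NMU, which encodes the peptide neuromedin U, was at 239, and MYL4, which encodes an embryonic and atrial myosin light chain, at 185, again listed at 0 elsewhere. The 5 low genes with the largest distance were listed at 0 in K562. GMFG, an actin regulator of blood cells, was at 779 in THP-1, 374 in the library labelled MOLM13 and 719 in HL60. TOMM6, a subunit of the mitochondrial import complex, was at 592, 250.5 and 358, and WDR83OS, a subunit of a membrane protein insertion complex, at 181, 153 and 232. PLEK, the protein kinase C substrate pleckstrin, was at 138, 137 and 133, and TMSB4X, the actin-binding thymosin beta 4, at 178, 112 and 404.

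Of 10 globins, 5 had a scaled TPM of at least 1 in any line, and the rest lay under 1 in every line, K562 included. Over these 5 the median log2 difference between K562 and the mean of the other 3 lines was 8.66, with 4 of 5 high. HBD, the delta globin gene, was at 13.4 in K562 and listed at 0 elsewhere. The globin medians were -2.89 in THP-1, -1.28 in the library labelled MOLM13 and -2.89 in HL60. Erythroid genes other than globins had a median of 3.12 in K562, with 11 of 24 members high. GYPB, a red cell surface gene, was at 91.5 in K562 and listed at 0 elsewhere, and HEMGN, a nuclear factor of erythroid cells, was at 210 in K562 and 10.0 in the library labelled MOLM13. CA2, a carbonic anhydrase, went the other way, at 2066 in THP-1, 189 in the library labelled MOLM13 and 32.0 in HL60 and listed at 0 in K562. The erythroid medians were -0.72 in THP-1, -0.73 in the library labelled MOLM13 and -1.33 in HL60. Heme synthesis genes had a median of 0.63 in K562 and -0.62 in THP-1, and of -0.19 in the library labelled MOLM13 and 0.28 in HL60, which lay inside the random range. FECH, the last enzyme of heme synthesis, was at 40.4 in K562 against 5.40 to 9.597 elsewhere, and PPOX, the enzyme before it, at 41.8 against 8.66 to 9.18. ALAD, an early enzyme of the same pathway, was listed at 0 in K562 and at 17.4 in HL60.

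Cancer-testis genes had a median of 4.65 in K562, with 6 of 9 members high, and of -1.55, -1.57 and -1.55 in THP-1, the library labelled MOLM13 and HL60. PRAME, a leukemia-associated antigen, was at 886 in K562 against 48.5, 11.6 and 66.3, and the X-linked antigens MAGEC1, MAGEC2 and CTAG2 were at 29.04, 27.8 and 25.2 and listed at 0 in THP-1 and HL60. MAGEB2, of the same family, was highest in THP-1 at 78.4. Mitochondrially encoded proteins, subunits of the respiratory chain, had a median of 1.197 in K562, with 8 of 13 members over 1 log2 unit higher. MT-ND4 was at 985 in K562 against 152 to 262 elsewhere, MT-ND4L at 1572, MT-ND6 at 1004 and MT-ND2 at 533, all subunits of complex I. The mitochondrial medians were -1.06 in THP-1, -0.02 in the library labelled MOLM13, inside the random range and with a mean of 0.03, and -0.29 in HL60. Epithelial and fibroblast genes had a median of 0.92 in K562 and -0.64 in THP-1, and of 0.04 in the library labelled MOLM13 and -0.23 in HL60, inside the random range. The simple keratins KRT8, KRT18 and KRT19 were at 151, 257 and 90.1 in K562 and at 125, 219.8 and 41.3 in the library labelled MOLM13, against 3.60 to 19.5 in THP-1 and HL60. ACTA2, a smooth muscle actin, was listed at 0 outside HL60, where it was at 8.23.

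In all, 206 protein-coding genes were high in K562, of which 105 were listed at 0 in the other 3 lines, and 432 were low, of which 370 were listed at 0 in K562. Those 432 include the ribosomal protein gene RPS27A, so a listing at 0 is reported as such and not as absence. Among 62 low genes above 0, chosen for naming after their values were seen, CASP4, an inflammatory caspase, was at 0.0230 against 39.4 to 82.3, AIF1, a macrophage calcium-binding protein, at 9.21 against 325 to 875, PSMB8, an immunoproteasome subunit, at 0.616 against 47.6 to 399.8, and ARHGAP15 and PTPRC (CD45, a phosphatase of leukocytes) at 5.47 and 3.81. High genes with no other line at 0, also chosen later, included ANK1, the red cell ankyrin, at 28.8, ALDH1A2, a retinoic acid enzyme, at 32.4, MAP1A at 10.6 and the transcription factor SMAD4 at 55.4. SMAD4 had 853 footprint equivalents in K562 and 759 in the less deep library labelled MOLM13, where its scaled TPM was 7.95. Aligned bases therefore did not set K562 apart for SMAD4. Leaving out genes listed at 0 in any line left 29 high and 62 low genes in K562, and leaving out the library labelled MOLM13 gave 523 and 845.

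The primary granule, interferon-stimulated and MHC class II lists lay above the random range in THP-1, with 5 of 15, 8 of 28 and 4 of 8 members high. The primary granule list did so in HL60 as well, and the interferon list only with genes listed at 0 kept. H4C6, a histone H4 gene on chromosome 6 (26240393 to 26240793, plus strand), was at 2815 in THP-1 (95% Poisson interval 2779 to 2852), 251-fold above the 11.2 of the library labelled MOLM13; other H4 genes encode the same protein, so its share is uncertain. PPP1R27, a phosphatase regulator, was at 737, 188-fold above the 3.92 of HL60. C1orf54 was at 209, the metallothionein MT1E at 137 and the readthrough gene NDUFC2-KCTD14 at 134, each listed at 0 in the other 3 lines. Genes low in THP-1 were MRPL23, a mitochondrial ribosomal protein, at 36.7 to 73.1 elsewhere, OIP5, a centromere factor, at 24.9 to 32.5, ANXA3, a phospholipid-binding annexin, at 20.7 to 30.6, and RAC3, a small GTPase, at 14.7 to 49.4, all listed at 0 in THP-1. The readthrough gene PPAN-P2RY11, which shares exons with its parent genes, was at 0.00152 against 22.0 to 29.9. RAC3 fell short of the size rule with a pseudocount of 5, at a log2 difference of -1.98.

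MHC class II genes, which present antigen to helper T cells, had a median of 3.91 in THP-1, with 4 of 8 members high. CD74, the invariant chain, was at 281 in THP-1, 3.05 in the library labelled MOLM13 and 15.3 in HL60, HLA-DRA at 48.6 in THP-1 and 4.91 in HL60, and HLA-DRB1 and its close copy HLA-DRB5 at 114 and 30.8 and listed at 0 elsewhere. The MHC class II medians were -1.34 in K562 and -1.15 in HL60, inside the random range but outside it with unmatched lists and without the library labelled MOLM13, and -1.85 in the library labelled MOLM13, which moved inside the range with aligned bases not divided by length (-1.97) and with a pseudocount of 0.1 (-2.01). Monocyte and macrophage genes had a median of 1.65 in THP-1 and 1.55 in HL60, with 8 and 4 of 25 members high, and of -1.94 in K562 and -1.64 in the library labelled MOLM13, where 13 members were listed at 0 and the 7 members above 0 in every line gave 0.32, inside the random range. The lysosomal protein CD68 was at 169.6 in THP-1 and 25.2 in HL60, the Fc receptor chain FCER1G at 458 and 107, the chemokine receptor CCR2 at 139 and 0.529, and the phagocyte oxidase subunit CYBB at 13.3 and 247. Interferon-stimulated genes had a median of 1.15 in THP-1, with 8 of 28 members high, of -1.02 in K562, of -0.53 in the library labelled MOLM13 and of -0.58 in HL60, inside the random range. The antiviral membrane protein IFITM3 was at 135 in THP-1 and 3.17 in HL60, and the transcription factor IRF9 at 22.2 against at most 0.318 elsewhere. RSAD2 (viperin) was highest in the library labelled MOLM13 at 48.8, and IFI30, a lysosomal thiol reductase, was listed at 0 there and at 69.0, 41.1 and 90.0 in K562, THP-1 and HL60. Without genes listed at 0 in any line, 13 interferon members gave medians of -0.39 in K562, 0.13 in THP-1 and 0.48 in the library labelled MOLM13, all inside the random range.

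HOXA cluster genes and their partners, regulators of blood progenitors, had a median of 1.07 in THP-1, with 10 of 18 members over 1 log2 unit higher, and of -0.91 in K562. The medians of 0.25 in the library labelled MOLM13 and -0.49 in HL60 lay inside the random range, and outside it at 0.93 and -1.42 without genes listed at 0. SATB1, a chromatin organizer, was at 106 in THP-1 and 34.5 in the library labelled MOLM13, ZEB2 at 64.1 against 4.89 to 10.7, and MEF2C at 87.9 in THP-1 and 32.2 in K562, all transcriptional regulators. HOXA11 was at 6.26 in HL60 and listed at 0 elsewhere. THP-1 had 396 high genes, of which 162 were listed at 0 in the other 3 lines, and 53 low genes, of which 33 were listed at 0 in THP-1. High genes with no other line at 0, chosen after their values were seen, included IRF8, a monocyte transcription factor, at 558 against at most 3.32, AGT (angiotensinogen) at 226, the actin regulator CAP1 at 8719 against 126 to 258, and EXO5 at 326. Low genes above 0, chosen in the same way, included TFDP2 at 0.753, MAGED1 at 4.23, IQGAP2 at 0.684 and the actin cross-linker FLNA at 8.34 against 87.6 to 147. Leaving out genes listed at 0 in any line left 88 high and 20 low genes.

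With genes listed at 0 kept, stem cell and T cell genes were high in the library labelled MOLM13, and granule and monocyte genes were low there. Without them the stem cell and monocyte medians lay inside the random range, and too few T cell and granule members were left for a median. CD96, a receptor of T and NK cells and of leukemic stem cells on chromosome 3 (111292719 to 111665750, plus strand), was at 517 (95% Poisson interval 507 to 528), 275-fold above the 1.88 of THP-1. The progenitor antigen CD34 was at 194 against at most 0.427, and HPGDS, the prostaglandin D synthase of mast cells, at 126 and listed at 0 elsewhere. SMIM24 was at 231, 227-fold above HL60, and CRISP3, a secreted granule protein, at 377, 145-fold above THP-1. GTSF1, a gametocyte factor, was at 1.17 there against 270.2 in K562, 366 in THP-1 and 187 in HL60. The other 4 low genes with the largest distance were listed at 0 in this library. They were TPI1, a glycolytic enzyme, at 83.4 to 264 elsewhere, RPL26, a ribosomal protein, at 69.3 to 175, CIAO2A, an iron-sulfur assembly factor, at 52.6 to 133, and RFXANK, a regulator of MHC class II genes, at 49.5 to 117.

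Stem and progenitor genes had a median of 2.49 in the library labelled MOLM13, with 6 of 14 members high, and of -1.39 in K562, -0.70 in THP-1 and -1.17 in HL60. The transcription factor ERG was at 44.6 and listed at 0 elsewhere. CD33, a myeloid surface antigen, was higher in THP-1 at 49.2 and HL60 at 68.3 than in this library at 5.46, and was listed at 0 in K562. The receptor gene FLT3 was listed at 0 in this library, and 1.83 in THP-1 was its highest value. MEIS1, a HOXA partner, was listed at 0 there and in HL60. T and NK cell genes had a median of 2.60, with 6 of 10 members high, and of -1.09 in K562, -0.84 in THP-1 and -1.09 in HL60. CD3D, a chain of the T cell receptor complex, was at 891 against 3.37 to 49.0, and CD247, another such chain, at 39.4 and listed at 0 elsewhere. CD4 was at 134 in THP-1 and 257 in HL60 against 0.466 here, and NKG7, a cytotoxic granule protein, at 42.0 in THP-1 and 23.5 here. With genes listed at 0 in any line left out, 3 stem and progenitor members remained and the medians were 0.11 in this library and 0.46, 1.10 and 0.62 in K562, THP-1 and HL60. With this library left out, the stem and progenitor medians were -0.51 in K562, 0.52 in THP-1 and -0.75 in HL60 and the T and NK cell medians 0.36, 0.82 and -1.11, all inside the random range. The T and NK cell median of HL60 was then as low as with all 4 libraries, over 5 members, while those of K562 and THP-1 changed sign.

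The library labelled MOLM13 had 229 high genes, of which 113 were listed at 0 in the other 3 lines, and 175 low genes, of which 151 were listed at 0 in it. High genes with no other line at 0, chosen after their values were seen, included the cytokine IL32 at 775, 74.1-fold above K562, MMRN1 (multimerin) at 47.9, HDC, the histamine-forming enzyme, at 40.2, and PCDH10 at 61.0. Low genes above 0, chosen in the same way, included the calponin CNN2 at 0.191 against 42.4 to 180.3, PFDN5, a prefoldin subunit, at 20.3 against 334 to 526, CHMP4A at 0.155 and ZNHIT1 at 10.2. Megakaryocyte and platelet genes had medians of 0.66 in this library, 0.58 in K562 and -0.67 in THP-1, inside the random range, and of -1.34 in HL60, which moved inside it under 4 settings; the K562 mean was -0.27, of opposite sign. The platelet integrin ITGA2B was at 82.4 in this library, 19.2 in K562 and 3.69 in HL60, FLI1 was listed at 0 in K562 and at 22.1 to 27.2 elsewhere, NRGN was at 30.3 in THP-1 alone, and the chemokine PPBP at 5.85 in HL60 alone. Leaving out genes listed at 0 in any line left 35 high and 24 low genes in this library, and turned the monocyte and macrophage median to 0.32 over 7 members.

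The primary and late granule lists lay above the random range in HL60, with 4 of 15 and 3 of 11 members high, and 8 of 33 histone genes were low. Both granule lists also lay above it in THP-1. MPO, the myeloperoxidase of primary granules on chromosome 17 (58269855 to 58280935, minus strand), was at 6359 in HL60, 165-fold above the 38.6 of THP-1, and at 13.4 in the library labelled MOLM13. BPI, a bactericidal granule protein, was at 368, 146-fold above THP-1. CCDC58 was at 108 and MTLN, which encodes a mitochondrial micropeptide, at 87.2, both listed at 0 elsewhere, and PTPRCAP, a CD45-associated protein, was at 111. H3C7, a histone H3 gene, was at 21.7 in HL60 against 1222 to 1657 elsewhere, and H2AC13, a histone H2A gene, at 5.97 against 167 to 219. Near-identical histone copies make the split between such genes uncertain. EPB41L2, a membrane skeleton protein, at 34.1 to 55.3 elsewhere, CPVL, a carboxypeptidase, at 30.6 to 41.1, and AC006064.6, which overlaps another gene, at 56.5 to 84.2, were listed at 0 in HL60.

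Primary granule genes had a median of 4.13 in HL60 and 3.80 in THP-1, with 4 and 5 of 15 members high. The median was -4.22 in K562, where 12 members were listed at 0, and -2.56 in the library labelled MOLM13, where 3 were. The proteases ELANE, AZU1 and CTSG were at 1504, 2065 and 3548 in THP-1, at 104, 337 and 2288 in HL60, at 2.60, 2.49 and 11.8 in the library labelled MOLM13, and listed at 0 in K562. Late granule and mature neutrophil genes had a median of 3.51 in HL60, with 3 of 11 members high, and of 1.56 in THP-1. Their median was -2.94 in K562, where 10 members were listed at 0, and -1.85 in the library labelled MOLM13, where 5 were. The calcium-binding alarmins S100A8 and S100A9 were at 2033 and 3030.4 in HL60, 995 and 988 in THP-1, and listed at 0 and at 10.7 in the library labelled MOLM13. CEBPE, a transcription factor of granulocytes, was at 229.5 in HL60 against at most 4.63. The late granule median of THP-1 moved inside the random range at 0.50 with a pseudocount of 5 and at 0.94 without division by length.

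HL60 had 175 high genes, of which 82 were listed at 0 in the other 3 lines, and 159 low genes, of which 56 were listed at 0 in HL60. Low genes outnumbered high ones with rescaled TPM (219 high, 270 low) and with aligned bases not divided by length (243 high, 323 low), so no direction prevailed under all scalings. High genes with no other line at 0, chosen after their values were seen, included the chemokine CCL2 at 221, 28.5-fold above the library labelled MOLM13, CYBB, 18.6-fold above THP-1, TSPAN14 at 188, FAM204A at 38.9 and CEACAM6, an adhesion molecule of granulocytes, at 136. TSPAN14 had 6144 footprint equivalents in HL60 against 580 to 1181, and FAM204A 1101 against 223 to 394, with HL60 the deepest library. The distances of TSPAN14 and FAM204A in TPM are thus larger than those in aligned bases. Low genes above 0, chosen in the same way, included the linker histone H1-5 at 13.001 against 306 to 2218, H2BC9 at 2.77 against 57.4 to 243, and TCEAL9 at 0.679. Core and linker histones had 8 of 33 members low in HL60 and 8 over 1 log2 unit higher, with a median of 0.20 and a mean of -0.75 of opposite sign. Their medians were -0.11 in K562, 0.04 in THP-1 and 0.22 in the library labelled MOLM13, where it lay outside the random range by a small distance. Leaving out genes listed at 0 in any line left 32 high and 103 low genes in HL60.

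**Figure D2:**
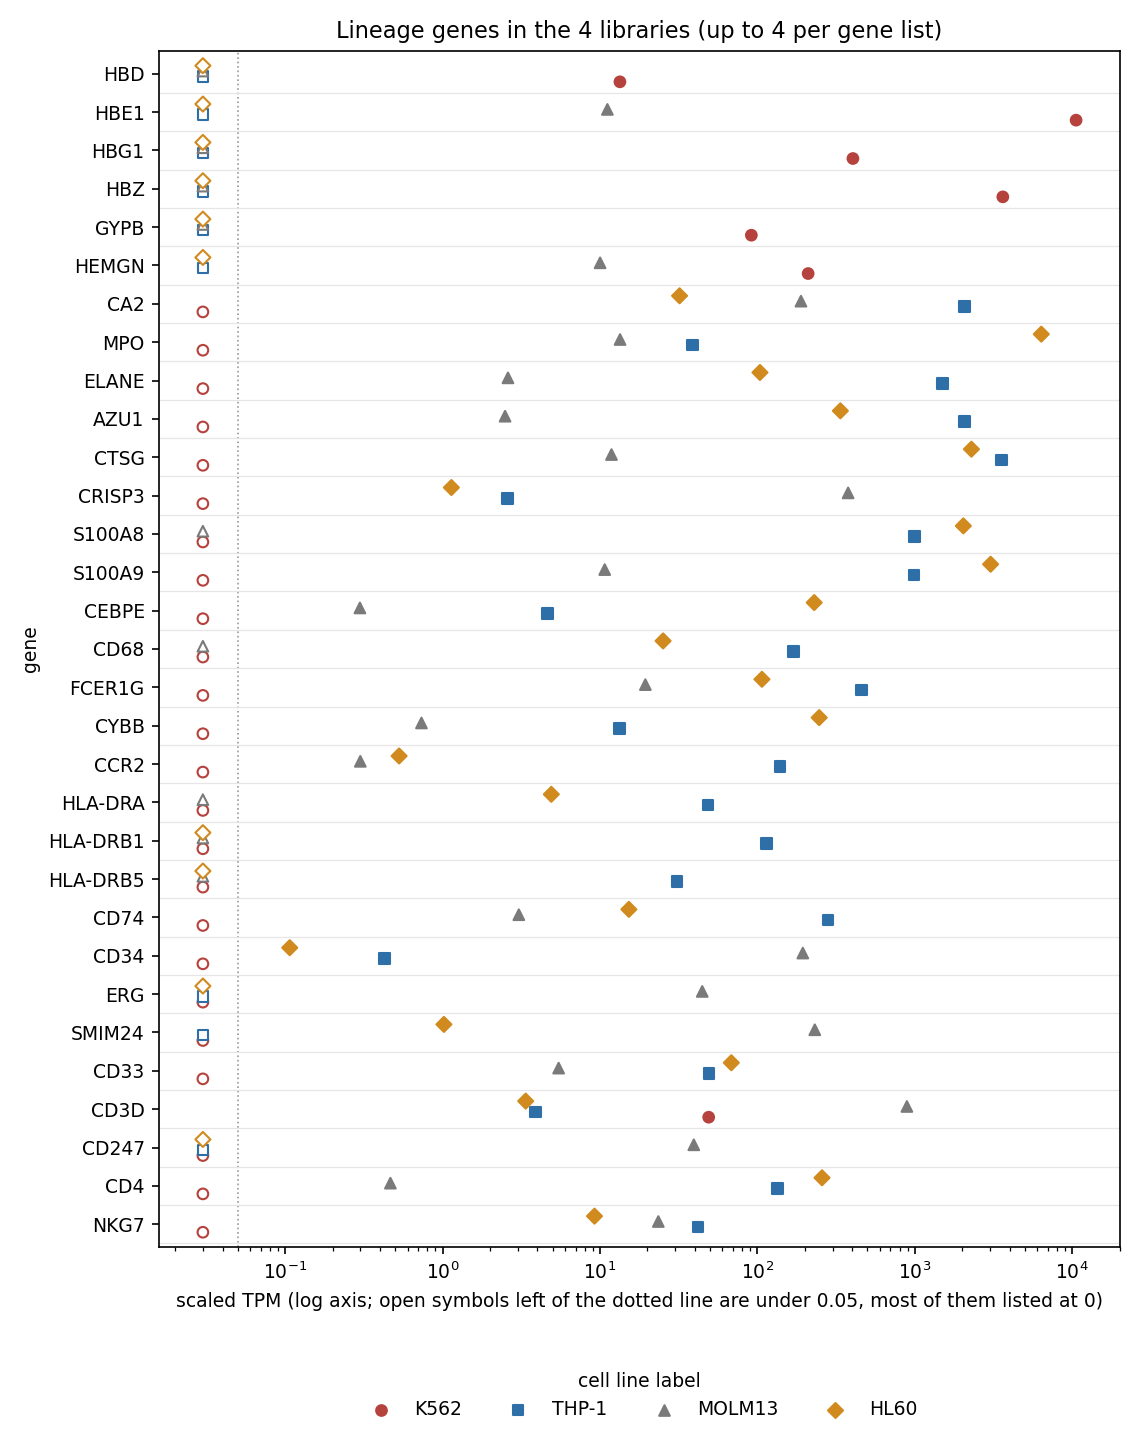
Scaled TPM on a log axis of up to 4 members of each of 8 lineage gene lists, with 1 point per library and line; open symbols at the left edge are values under 0.05, most of them listed at 0. HBE1 sits at 10580 in K562, MPO at 6359 in HL60, CTSG at 3548 in THP-1 and CD3D at 891 in the library labelled MOLM13.

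Several lists set HL60 or K562 apart by smaller distances. MHC class I and antigen processing genes had medians of 1.83 in HL60 and 1.41 in THP-1, and of -1.93 in K562 and -0.85 in the library labelled MOLM13, with 14 of 15 members over 1 log2 unit lower in K562. HLA-B was at 816 in HL60, 456 in THP-1, 29.1 in the library labelled MOLM13 and 21.2 in K562, and the immunoproteasome subunit PSMB9 at 62.6, 164, 9.92 and 2.18. ERAP2, a peptide-trimming enzyme, was at 28.9 in HL60 and listed at 0 in K562. Glycolysis genes had a median of 1.201 in HL60, with 11 of 20 members over 1 log2 unit higher, and of -0.03, -0.25 and -0.26 in K562, THP-1 and the library labelled MOLM13; the mean in K562 was 0.33, of opposite sign. The lactate exporter SLC16A3 was at 134 in HL60 and 2.66 in K562, the glucose transporter SLC2A3 at 56.3 in K562 and listed at 0 in THP-1, and ALDOC, an aldolase, listed at 0 in the library labelled MOLM13 and 10.7 in HL60. Cholesterol synthesis genes had medians of 0.49 in HL60, inside the random range without the library labelled MOLM13 (0.38), and -0.60 in K562, inside it with unmatched lists, and of 0.15 in THP-1 and -0.02 in the library labelled MOLM13, whose mean was 0.10, of opposite sign. The sterol isomerase EBP was at 471 in HL60 against 99.2 to 161, HSD17B7 at 13.98 and listed at 0 in K562, SQLE (squalene epoxidase) lowest in HL60 at 24.2, and MVK (mevalonate kinase) listed at 0 in K562.

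Genes of the translation machinery stood apart by small distances, and those of the cell cycle and the integrated stress response did not stand apart in any line, except the stress response in the library labelled MOLM13 at -0.34 with aligned bases not divided by length. Cytosolic ribosomal proteins had a median of 0.57 in HL60, with 14 of 78 members over 1 log2 unit higher, of -0.22 in THP-1, -0.25 in the library labelled MOLM13 and -0.04 in K562, the first 3 outside the random range. RPS27A was listed at 0 in K562, and RPL26 and RPS27 in the library labelled MOLM13, while RPS3A was at 16.5 in HL60 alone; these genes have many processed copies, and their values are uncertain. Translation factors had a median of 0.20 in K562, outside the random range, and of -0.14, -0.08 and -0.03 in THP-1, the library labelled MOLM13 and HL60. With deposited TPM the K562 value was -0.14, but protein-coding genes in general were also lower there, with a median of -0.35 over 3382 genes. The list stayed above the random range in that setting, at percentile 99.08. The elongation factor EEF1G was at 112 in THP-1 and listed at 0 in K562, EIF3E at 123 to 540.5, PABPC4 at 9.72 in HL60 against 51.6 to 214, and GSPT1 at 246 in K562. The THP-1 mean for translation factors was 0.11, of opposite sign to its median. Cell cycle genes had medians of 0.06, 0.05, 0.12 and -0.03 in K562, THP-1, the library labelled MOLM13 and HL60, with means of -0.04 in THP-1 and under 0 in the library labelled MOLM13 of opposite sign. Among them CDC20, a mitotic activator, was at 466 in THP-1 against 77.8 to 163, the cyclin CCNE1 was listed at 0 in the library labelled MOLM13, CCNE2 was at 50.9 in THP-1 and CCND2 at 85.3 in HL60. Integrated stress response genes had medians of 0.07, 0.27, -0.11 and -0.05 in the same order. The pseudokinase TRIB3 was listed at 0 in the library labelled MOLM13 and at 9.603 to 14.8 elsewhere, CHAC1 was at 8.88 in K562, VLDLR at 23.2 in THP-1, and XBP1 at 11.9 in K562 against 77.99 to 112.

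Of 14 B cell genes, 4 had a scaled TPM of at least 1 in any line, with medians of -1.15, 0.93, -0.44 and 0.65, inside the random range. CD79A was at 3.60 in HL60 alone, IGHM at 6.12 and BANK1 at 6.94 in THP-1, BANK1 at 12.4 in the library labelled MOLM13, and IGKC at 1.70 to 27.9. Loci often altered in leukemia lines had medians of -0.32, -0.34, 0.46 and -0.38, inside the random range, with means of 0.04 in THP-1 and 0.24 in HL60 of opposite sign to the medians. MTAP, next to the CDKN2A tumour suppressor on chromosome 9, was listed at 0 in K562 and at 0.503 in THP-1, 32.1 in the library labelled MOLM13 and 50.5 in HL60. CDKN2A was at 24.9, 1.09, 38.4 and 7.19, the myeloid transcription factor CEBPA at 0.0259, 26.7, 4.199 and 15.9, and SPI1 (PU.1) at 0, 148, 9.19 and 218. MYC was highest in HL60 at 792 against 124 to 206. Of 112 combinations of list and line, 60 lay outside the central range of random lists. Chance gives 5.6 for genes drawn at random, but members of a real list can vary together, so 5.6 is no error rate for these lists. Of the 60, 43 stayed outside under all planned settings. The others were stem and progenitor genes in K562, THP-1 and HL60, T and NK cell genes in K562 and THP-1, globins, MHC class II, interferon-stimulated genes and histones in the library labelled MOLM13, and late granule, epithelial and ribosomal protein genes in THP-1. In K562 they were HOXA genes, cholesterol synthesis and translation factors, and in HL60 megakaryocyte and mitochondrially encoded genes. Lost only without genes listed at 0 were stem, monocyte and ribosomal protein genes in the library labelled MOLM13 and interferon-stimulated genes in K562 and THP-1. Lost only without that library were T and NK cell and cholesterol synthesis genes in HL60. Some pairs inside the range moved outside it under a setting. They were HOXA and epithelial genes in the library labelled MOLM13 and HL60, MHC class II in K562 and HL60, megakaryocyte genes in K562, THP-1 and the library labelled MOLM13, and glycolysis in THP-1. They were also the stress response and loci altered in leukemia in the library labelled MOLM13, B cell genes in K562, and interferon-stimulated genes, small nucleolar RNA hosts and nuclear lncRNAs in HL60. The 4 differences of a list are linked, since a list high in 1 line is low against it in the others.

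**Figure D3:**
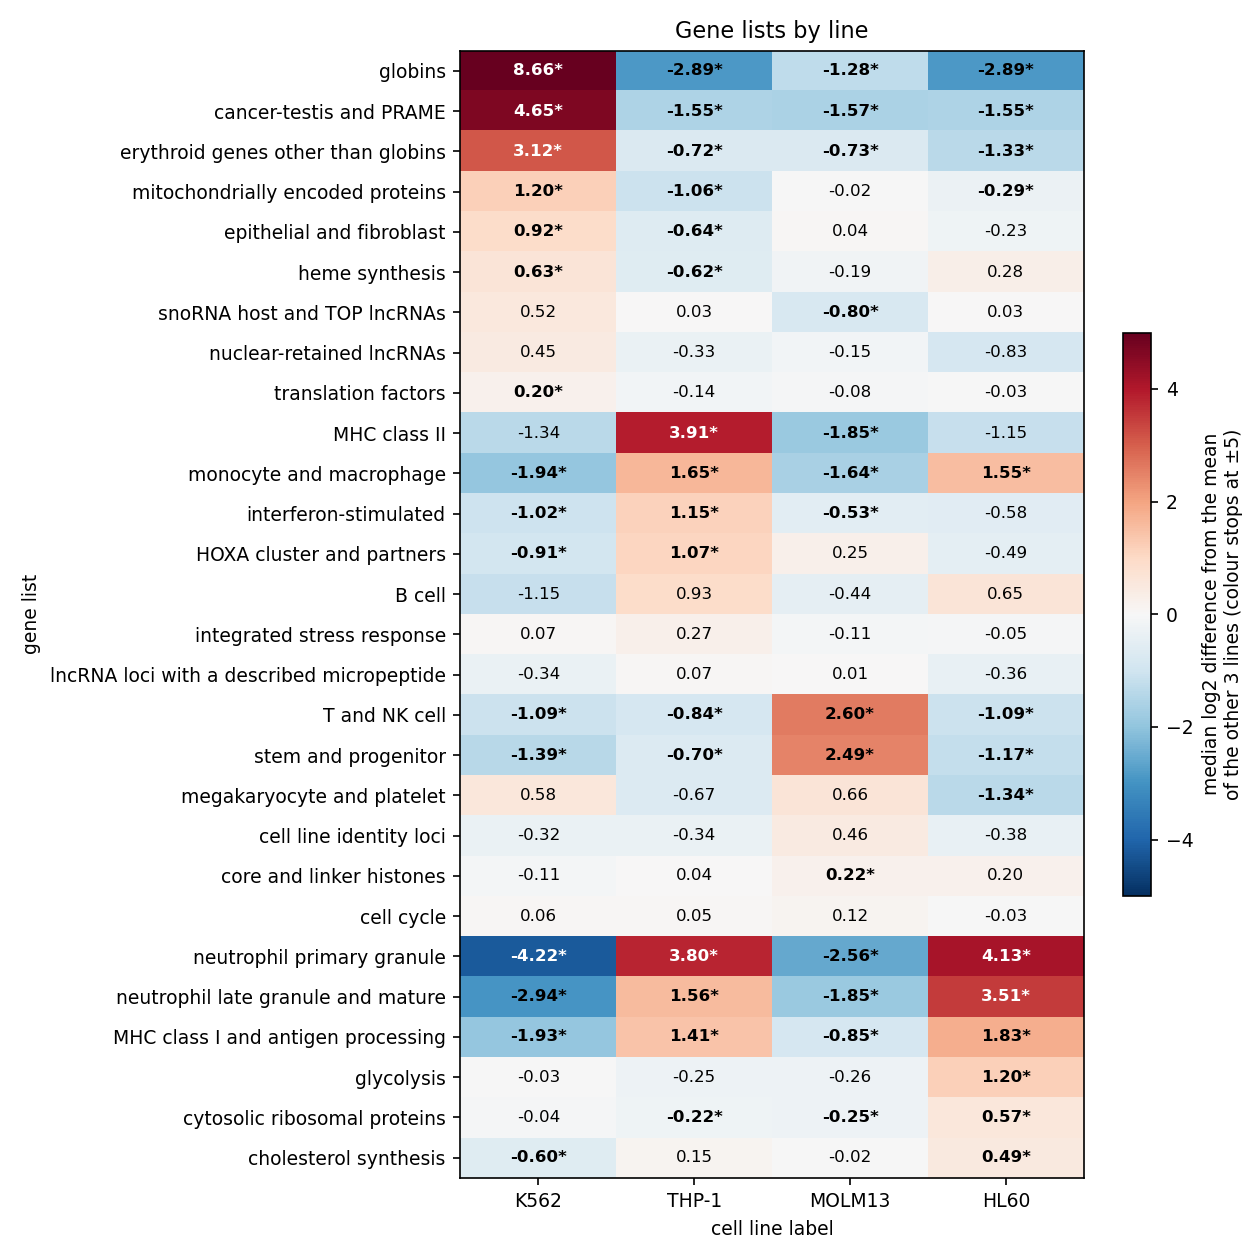
Median log2 difference of each gene list between a line and the mean of the other 3, with colour from blue (lower) to red (higher) and an asterisk outside the central 95% of matched random lists. Globins reach 8.66 in K562, MHC class II 3.91 in THP-1, T and NK cell genes 2.60 in the library labelled MOLM13 and primary granule genes 4.13 in HL60.

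Members went against their list's median by over 1 log2 unit in most lists. Among erythroid genes they were CA2 and TRIM58 in K562 and THP-1, RHAG, GFI1B, XK, CA2 and TRIM58 in the library labelled MOLM13, and NFE2, EPOR and CA1 in HL60; RHAG, a red cell membrane protein, was at 464 in K562 and 455 in the library labelled MOLM13 against 3.82 and 1.09. Among heme synthesis genes they included ALAS1 and ALAD in K562, ALAD in THP-1 and FECH in HL60, and among cancer-testis genes they were MAGEB2 in 3 lines, MAGEA4 in THP-1 and MAGEA6 in the library labelled MOLM13. Among granule genes they were BPI, CST7, DEFA4, CRISP3 and PADI4 in THP-1, PRSS57, CST7 and CRISP3 in the library labelled MOLM13, and PRSS57 and CRISP3 in HL60. Among monocyte genes they were VCAN in K562, VCAN and AIF1 in the library labelled MOLM13, CLEC7A in THP-1, and VCAN, CTSB and CCR2 in HL60. Among MHC genes they included HLA-DPB1 in K562, THP-1 and the library labelled MOLM13, HLA-DMA in K562, and ERAP2 in THP-1 and the library labelled MOLM13. Among interferon-stimulated genes they were IFI30 and IFITM1 in K562, IFITM1 and RSAD2 in THP-1, IFI16, IFI44, IFIT5, IFITM1, RSAD2, DDX58 and TRIM22 in the library labelled MOLM13, and IFI6, IFI27 and IFI30 in HL60. Among HOXA genes and partners they included HOXA5, MEIS1 and MEF2C in K562, ZEB2 in the library labelled MOLM13, and HOXA11 and RUNX2 in HL60. Among stem and progenitor genes they were KIT and MECOM in K562, FLT3, MYB, LMO2, CD33 and CD38 in THP-1, LMO2 and CD33 in the library labelled MOLM13, and CD33 in HL60. Against the T and NK cell median went CD3G in K562, CD4 and NKG7 in THP-1, and CD4 in the library labelled MOLM13 and HL60. Among epithelial and fibroblast genes they were COL1A2, COL3A1 and ACTA2 in K562, COL1A2 and COL3A1 in THP-1, CLDN4, LUM and ACTA2 in the library labelled MOLM13, and ACTA2 in HL60. Among megakaryocyte genes they were FLI1 and NRGN in K562 and THP-1, NRGN in the library labelled MOLM13, and PPBP and FLI1 in HL60, and among B cell genes IGKC in K562 and BANK1 in the library labelled MOLM13 and HL60. Among histones they included H2AC13 and H3C7 in K562, H4C2 in THP-1, H2AZ2, H2BC21 and H3-3A in the library labelled MOLM13, and H1-3, H1-5, H2AC8, H2AC13, H2BC9, H2BC13, H2BC14, H3C7 and H4-16 in HL60.

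Among ribosomal proteins the members against the median included RPL7, RPL9, RPL23, RPL26, RPL41, RPS10, RPS27 and RPS28 in K562, RPL7, RPL26, RPS27, RPS27A and RPSA in THP-1, RPL30, RPS26 and RPS27A in the library labelled MOLM13, and RPL30 and RPS20 in HL60. Among translation factors they were EEF1G, EIF3E and EIF3L in K562, EEF1G, EIF3E and PABPC4 in THP-1, and EIF3L in HL60. Among cell cycle genes they were MKI67 and CDC20 in K562, PCNA, CCND1 and CCND2 in THP-1, MCM7, CCNE1 and CCND1 in the library labelled MOLM13, and RRM2, CCND1 and CCND2 in HL60. Among glycolysis genes they were HK1, PFKM, TPI1, ENO2 and SLC2A3 in K562, TPI1, SLC2A1 and SLC16A3 in THP-1, PFKP and ENO2 in the library labelled MOLM13, and HK1, PFKP, ENO2 and SLC2A1 in HL60. Among cholesterol synthesis genes they were SQLE in K562, DHCR7 in THP-1, MVK and SC5D in the library labelled MOLM13, and SQLE and SC5D in HL60, and MT-ND1 went against the mitochondrial median in the library labelled MOLM13. Among stress response genes they were VLDLR, XBP1, DNAJB9 and SEL1L in K562, ASNS, SLC7A5, CEBPB and GPT2 in THP-1, SLC7A5, XBP1, PCK2 and GPT2 in the library labelled MOLM13, and TRIB3, ASNS, CEBPB and VLDLR in HL60. Among loci altered in leukemia lines they included CDKN2A and ABL1 in K562, FLT3, BCL2, MCL1, CEBPA, CEBPD, SPI1 and RUNX1 in THP-1, MCL1, CEBPD and SPI1 in the library labelled MOLM13, and MYC, MTAP, BCR, CEBPA and SPI1 in HL60.

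Footprint signal on lncRNA genes, the subject of the series, was found at 414 of 14841 genes in K562 (2.79%), 472 in THP-1 (3.18%), 370 in the library labelled MOLM13 (2.49%) and 349 in HL60 (2.35%), counting genes with a scaled TPM of at least 1 and at least 600 aligned bases. Of 881 such genes in any line, 118 had signal in all 4 and 488 in 1 line. Their median level was 3.74, 3.83, 4.12 and 2.62 scaled TPM, against 12.5, 12.4, 13.1 and 11.7 for protein-coding genes chosen by the same rule. The files were made without a strand option, so reads of a gene and its antisense partner cannot be told apart. Without lncRNA genes that share exons with another gene on either strand, 112, 123, 79 and 77 genes of 9181 had signal, 16 of them in all 4 lines and 188 in 1 line.

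The 10 lncRNA genes without exon overlap and with the highest minimum over the 4 lines were led by AL049796.1 on chromosome 1 (93847174 to 93848939, plus strand), at 95.03 in K562, 122 in THP-1, 73.3 in the library labelled MOLM13 and 56.3 in HL60. AC124068.2 on chromosome 15 (89335053 to 89336161, plus strand) was at 54.4, 161, 48.8 and 36.5, and SNHG19, a small nucleolar RNA host gene on chromosome 16 (2154797 to 2155358, minus strand), at 45.2, 31.2, 106 and 23.5. AL592295.4 was at 18.3 to 97.8, AD000090.1 at 14.6 to 64.9, GIHCG at 9.30 to 40.2 and SCOC-AS1 at 9.14 to 15.97. AC104237.3 was at 177 in K562 against 5.52 to 32.5, AL118516.1 at 20.2 in K562 against 3.74 to 6.06, and AC011445.1 at 3.29 to 29.7.

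**Figure D4:**
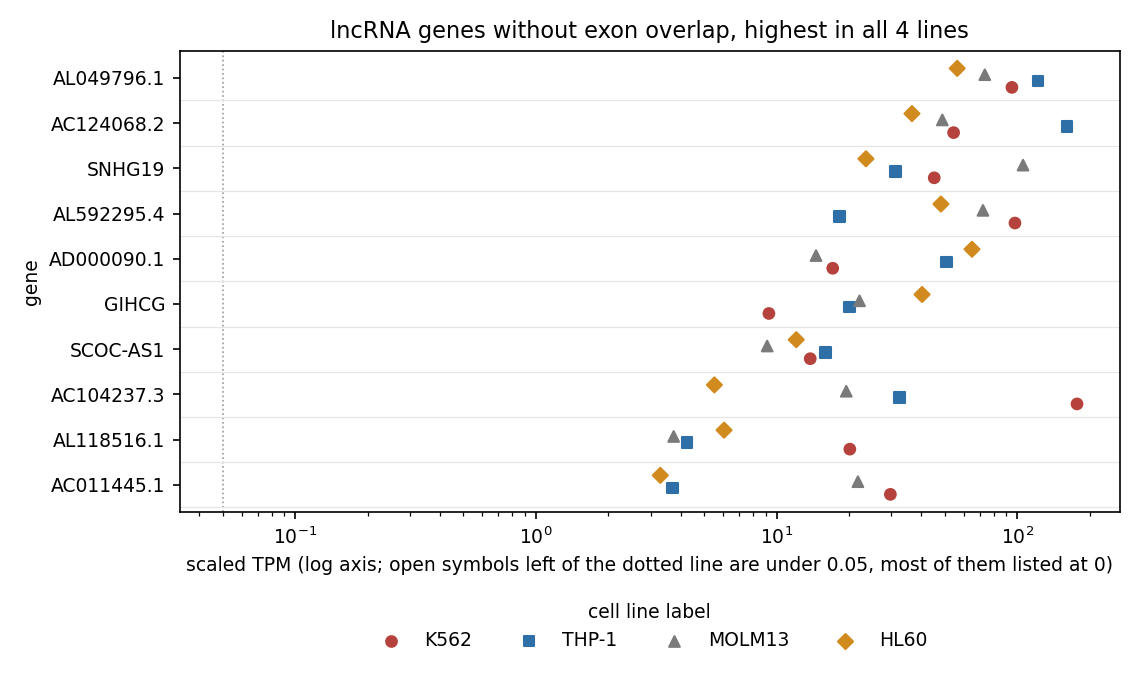
Scaled TPM on a log axis of the 10 lncRNA genes without exon overlap that have the highest minimum over the 4 libraries, with 1 point per library. AL049796.1 lies between 56.3 and 122, and AC104237.3 spans 5.52 in HL60 to 177 in K562.

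By the size rule 50 lncRNA genes were high in K562, 68 in THP-1, 24 in the library labelled MOLM13 and 18 in HL60, of which 20, 30, 9 and 6 shared no exon with another gene. LINC01029 on chromosome 18 (77970637 to 77993731, minus strand) was at 28.1 in K562 and EPS15-AS1 at 20.0, with AC093512.1, which overlaps another gene, at 25.1. LINC02169 on chromosome 16 (54245544 to 54270879, minus strand) was at 120.1 in THP-1, AL596442.1 at 70.0 and the overlapping AL360012.1 at 124. AL359458.1 on chromosome 6 (49823712 to 49824782, minus strand) was at 123 in the library labelled MOLM13, and the overlapping AC008622.2 and AC091814.1 at 84.7 and 18.8. In HL60 the overlapping TRG-AS1, AC231981.1 and AC018754.1 were at 24.2, 24.02 and 15.8. All 12 were listed at 0 in the other 3 lines, except AC008622.2, at 0.353 in HL60.

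Small nucleolar RNA hosts and related lncRNAs had a median of -0.80 in the library labelled MOLM13 and of 0.52, 0.03 and 0.03 in K562, THP-1 and HL60, inside the random range; the THP-1 mean was -0.18, of opposite sign. SNHG8 was at 632 in K562, 54.2 in THP-1, 257 in the library labelled MOLM13 and 45.6 in HL60, SNHG3 at 311, 29.3, 155 and 94.1, SNHG12 at 49.9 in K562 against 6.58 to 14.6, and CYTOR at 13.3 in K562 and 2.95 in HL60. SNHG1, SNHG3, SNHG8, DANCR and CYTOR in THP-1, SNHG8 and SNHG19 in the library labelled MOLM13, and SNHG6, SNHG8 and SNHG19 in HL60 went against the median by over 1 log2 unit. lncRNAs known to be retained in the nucleus had medians of 0.45, -0.33, -0.15 and -0.83, inside the random range, with a THP-1 mean of 0.17. PVT1, next to MYC, was at 47.2 in K562 against 1.64 to 6.92, MEG3 at 5.65 in K562, HOXA11-AS at 8.99 in THP-1 and JPX at 0.973 to 13.4. HOTTIP and HOXA11-AS in K562, HOTTIP, HOXA-AS3, HOXA11-AS and JPX in THP-1, and HOTAIRM1, HOXA-AS2 and LINC-PINT in the library labelled MOLM13 went against the median. Loci with a described micropeptide had medians of -0.34, 0.07, 0.01 and -0.36 over 25 members, inside the random range, with means of under 0 in THP-1 and 0.05 in HL60 of opposite sign. That range came from lncRNA genes, although MTLN, a member of the list, is classed here as protein-coding. MTLN was listed at 0 outside HL60, NBDY was listed at 0 in K562 and at 8.85 to 18.2 elsewhere, and ASDURF was listed at 0 in K562 and at 10.4 to 29.3 elsewhere. SMIM30, LINC00467, LINC01128, CYTOR and SNHG8 in K562, MTLN, SMIM30, SMIM26, CYTOR, DLEU1 and SNHG8 in THP-1, MTLN, LINC01128, CYTOR and ZFAS1 in the library labelled MOLM13, and MTLN, DLEU1, NCBP2AS2 and ASDURF in HL60 went against the median.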

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

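The values in this part come from genes outside the comparisons of the report, each with over 5% of the deposited TPM of a library, and the search for them was made only after the data were seen. AC073140.1, a gene of 156 exon bases on chromosome 7 (148941483 to 148941638, plus strand) that was not classified, held 9.73% of the deposited TPM in K562, 6.66% in THP-1, 5.42% in the library labelled MOLM13 and 2.71% in HL60. MT-RNR2, the large mitochondrial ribosomal RNA, held 6.02%, 6.34% and 5.44% in the first 3 libraries and 4.54% in HL60. RNU1-67P, a copy of the U1 spliceosomal RNA on the X chromosome (119423742 to 119423905, plus strand), held 15.0% in K562, 0.788% in THP-1, 4.79% in the library labelled MOLM13 and 0.475% in HL60.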

How the results depend on the processing

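The settings without genes listed at 0 and without the library labelled MOLM13, and their tests, were chosen only after the results were seen; MOLM13 below stands for the library with that label. Of 60 list and line pairs outside the random range, 43 stayed outside with the same sign under all planned settings and 36 under all settings in which each was run; the settings without genes listed at 0 and without the library labelled MOLM13 each had 84 of 112 pairs. Of 52 high or low genes named by the rule fixed in advance, 51 kept their call under all settings in which each was run, the exception being RAC3. These 52 were chosen for the largest distances in the same data, so the count says nothing of the other calls. It also says nothing of genes that were named only later, such as SMAD4, TSPAN14 and FAM204A. Most of the 52 were listed at 0 in some line, so leaving out such genes could not test their calls. The share of high genes among all calls moved by under 10 points under each scaling, the most in HL60 with normalized aligned bases, by -9.46. Counts moved as the construction of a stricter or looser rule or a smaller gene set sets them; for all other values below the cause was not tested. No minimum of aligned bases and a scaled TPM of at least 0.5 left each count within 1.5 times its main value. At 600 aligned bases, counting error alone spans 61.7% to 153% of a value; whether depth limits the number of calls was not tested.

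With TPM rescaled over nuclear protein-coding genes, there were 342 high genes in K562 and 344 in MOLM13. There were also 99 low genes in THP-1 and 270 in HL60. Inside the random range now lay -0.84 for the HOXA cluster and partners list in K562, -1.22 for the megakaryocyte and platelet list in HL60 and -0.82 for the stem and progenitor list in THP-1.

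With normalized aligned bases, not divided by length, there were 316 high genes in K562. There were also 688 low genes in K562, 111 in THP-1, 301 in MOLM13 and 323 in HL60. Inside the random range now lay -1.97 for the MHC class II list in MOLM13, -1.23 for the T and NK cell list in K562, -0.91 for the megakaryocyte and platelet list in HL60, -0.14 for the mitochondrially encoded proteins list in HL60, 0.94 for the neutrophil late granule and mature list in THP-1, -1.41 for the stem and progenitor list in K562, -0.60 for the stem and progenitor list in THP-1 and 0.12 for the translation factors list in K562. Outside it now lay 0.70 for the cell line identity loci list in MOLM13, -0.34 for the glycolysis list in THP-1, -0.34 for the integrated stress response list in MOLM13, -0.89 for the megakaryocyte and platelet list in THP-1 and 1.38 for the megakaryocyte and platelet list in MOLM13.

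With a pseudocount of 0.1, there were 431 high genes in K562, 785 in THP-1, 462 in MOLM13 and 377 in HL60. There were also 867 low genes in K562, 181 in THP-1, 392 in MOLM13 and 485 in HL60. There were also 4154 genes apart for K562–THP-1, 2922 for K562–MOLM13, 4221 for K562–HL60, 3754 for THP-1–MOLM13, 2792 for THP-1–HL60 and 3855 for MOLM13–HL60. R was 0.803 for K562–THP-1, 0.848 for K562–MOLM13, 0.806 for K562–HL60, 0.834 for THP-1–MOLM13, 0.897 for THP-1–HL60 and 0.841 for MOLM13–HL60. Inside the random range now lay -2.01 for the MHC class II list in MOLM13, -2.36 for the globins list in MOLM13, -1.50 for the megakaryocyte and platelet list in HL60, -0.39 for the stem and progenitor list in THP-1 and -1.60 for the stem and progenitor list in HL60.

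With a pseudocount of 5, there were 63 high genes in K562, 157 in THP-1, 71 in MOLM13 and 77 in HL60. There were also 95 low genes in K562, 10 in THP-1, 35 in MOLM13 and 46 in HL60. There were also 915 genes apart for K562–THP-1, 512 for K562–MOLM13, 838 for K562–HL60, 736 for THP-1–MOLM13, 484 for THP-1–HL60 and 735 for MOLM13–HL60. Inside the random range now lay -0.33 for the T and NK cell list in THP-1, -0.22 for the epithelial and fibroblast list in THP-1, -0.22 for the interferon-stimulated list in MOLM13 and 0.50 for the neutrophil late granule and mature list in THP-1. RAC3 had a log2 difference of -1.98 in THP-1.

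With a log2 difference of at least 1, there were 651 high genes in K562, 1043 in THP-1, 791 in MOLM13 and 521 in HL60. There were also 904 low genes in K562, 235 in THP-1, 403 in MOLM13 and 662 in HL60. There were also 5421 genes apart for K562–THP-1, 3844 for K562–MOLM13, 5305 for K562–HL60, 5128 for THP-1–MOLM13, 3708 for THP-1–HL60 and 5170 for MOLM13–HL60.

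With a log2 difference of at least 3, there were 87 high genes in K562, 180 in THP-1, 101 in MOLM13 and 83 in HL60. There were also 211 low genes in K562, 17 in THP-1, 80 in MOLM13 and 46 in HL60. There were also 1166 genes apart for K562–THP-1, 852 for K562–MOLM13, 1128 for K562–HL60, 976 for THP-1–MOLM13, 566 for THP-1–HL60 and 931 for MOLM13–HL60.

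With genes listed at exactly 0 in any line compared left out, there were 29 high genes in K562, 88 in THP-1, 35 in MOLM13 and 32 in HL60. There were also 62 low genes in K562, 20 in THP-1, 24 in MOLM13 and 103 in HL60. There were also 933 genes apart for K562–THP-1, 402 for K562–MOLM13, 984 for K562–HL60, 985 for THP-1–MOLM13, 771 for THP-1–HL60 and 1112 for MOLM13–HL60.

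With the library labelled MOLM13 left out, there were 523 high genes in K562. There were also 845 low genes in K562. Inside the random range now lay -1.11 for the T and NK cell list in HL60, 0.38 for the cholesterol synthesis list in HL60, -0.94 for the megakaryocyte and platelet list in HL60, -0.23 for the mitochondrially encoded proteins list in HL60, -0.51 for the stem and progenitor list in K562 and -0.75 for the stem and progenitor list in HL60. Outside it now lay -1.73 for the MHC class II list in K562, -1.41 for the MHC class II list in HL60, -0.46 for the glycolysis list in THP-1, -0.72 for the interferon-stimulated list in HL60 and 1.65 for the megakaryocyte and platelet list in K562. The sign turned to give 0.36 for the T and NK cell list in K562, 0.82 for the T and NK cell list in THP-1 and 0.52 for the stem and progenitor list in THP-1.

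With at least 3000 aligned bases, there were 166 lncRNA genes with signal in K562, 258 in THP-1, 123 in MOLM13, 208 in HL60, 56 in all 4 lines, 221 in 1 line and 410 in any line.

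With a scaled TPM of at least 5, there were 176 lncRNA genes with signal in K562, 186 in THP-1, 162 in MOLM13, 109 in HL60, 49 in all 4 lines, 196 in 1 line and 350 in any line.

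With only lncRNA genes without exon overlap, there were 112 lncRNA genes with signal in K562, 123 in THP-1, 79 in MOLM13, 77 in HL60, 16 in all 4 lines, 188 in 1 line and 267 in any line.

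With a share of deposited TPM, the result was 37.8% of TPM on protein-coding genes in K562, 58.4% in THP-1, 53.1% in MOLM13 and 59.4% in HL60. The result was 1.203% of TPM on lncRNA genes in K562, 1.03% in THP-1, 1.07% in MOLM13 and 0.607% in HL60.

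With a ratio of coverage summed over genes, the 3′ untranslated ratios were 0.322 in K562, 0.3003 in THP-1, 0.314 in MOLM13 and 0.319 in HL60.

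With a mean coding coverage of at least 10, the 3′ untranslated ratios were 0.174 in THP-1, 0.141 in MOLM13 and 0.215 in HL60.

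With a scaled TPM of at least 1 in all 4 lines, r was 0.816 for K562–THP-1, 0.889 for K562–MOLM13, 0.819 for K562–HL60, 0.834 for THP-1–MOLM13, 0.879 for THP-1–HL60 and 0.825 for MOLM13–HL60.

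With deposited TPM with no further scaling, inside the random range now lay -0.58 for the epithelial and fibroblast list in THP-1. The sign turned to give -0.14 for the translation factors list in K562, but its percentile stayed above the random range at 99.08. Protein-coding genes in general were lower in K562 in this setting, with a median of -0.35 over 3382 genes.

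With random lists not matched on expression, inside the random range now lay -0.60 for the cholesterol synthesis list in K562, 0.22 for the core and linker histones list in MOLM13, -0.22 for the cytosolic ribosomal proteins list in THP-1, -0.29 for the mitochondrially encoded proteins list in HL60 and 0.20 for the translation factors list in K562. Outside it now lay -1.34 for the MHC class II list in K562, -1.15 for the MHC class II list in HL60 and 0.03 for the snoRNA host and TOP lncRNAs list in HL60.

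With genes listed at exactly 0 in any line left out, inside the random range now lay -0.24 for the cytosolic ribosomal proteins list in MOLM13, -0.39 for the interferon-stimulated list in K562, 0.13 for the interferon-stimulated list in THP-1 and 0.11 for the stem and progenitor list in MOLM13. Outside it now lay -1.56 for the B cell list in K562, 0.93 for the HOXA cluster and partners list in MOLM13, -1.42 for the HOXA cluster and partners list in HL60, 0.86 for the epithelial and fibroblast list in MOLM13, -1.10 for the epithelial and fibroblast list in HL60 and -1.79 for the nuclear-retained lncRNAs list in HL60. The sign turned to give 0.48 for the interferon-stimulated list in MOLM13, 0.32 for the monocyte and macrophage list in MOLM13, 0.46 for the stem and progenitor list in K562, 1.10 for the stem and progenitor list in THP-1 and 0.62 for the stem and progenitor list in HL60.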

Other observations

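The tests chosen only after the result was seen are those on K562 RNA, on granule genes at 0, on a wrong label and on translating ribosomes, and the settings without genes listed at 0 or without the library labelled MOLM13; the other tests were chosen before it. Small structural RNAs, which are not templates for translation, had median log2 differences of 0.41 in K562, 0.40 in THP-1, -0.26 in the library labelled MOLM13 and -0.18 in HL60 over 21 members. The HL60 and THP-1 extremes lay far from these medians. TERC, the telomerase RNA, was at 212 in THP-1 against 1.67 to 3.17 elsewhere, and the Y RNA RNY3 at 227 against 4.54 to 14.2. VTRNA1-3, a vault RNA, was at 466 in K562 and 13.2 in HL60, and SNORD118, a small nucleolar RNA, at 554 in K562 and 17.2 in THP-1. RNU4-1, RNU4-2, RNY3, RNY4, RN7SL3 and TERC in K562, RNU5A-1, VTRNA1-2 and SNORD118 in THP-1, VTRNA1-2, VTRNA1-3 and MT-RNR1 in the library labelled MOLM13, and RNU4-1 and RNU4-2 in HL60 went against the median by over 1 log2 unit.

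Some protein-coding genes were listed at exactly 0 in 1 library and had a scaled TPM of at least 10 in each of the other 3. They numbered 129 in K562 (3.43% of 3761), 7 in THP-1, 51 in the library labelled MOLM13 (1.42% of 3590) and 12 in HL60, 199 in all. Too few footprints are argued against, since Poisson sampling gave an expected 2.08e-07 such genes in K562, where the expected number was highest. Transfer of reads to a gene with overlapping exons was not decided. Over 72 genes with such a partner at a scaled TPM of at least 1 in any line, the partner with the largest log2 difference was taken. The median of these differences was 0.197 (-0.18 to 0.49). A partner far above the gene would rise little even if it took all its reads, so the value cannot decide. The share with a pseudogene named after the gene was 0.836 times that of other genes (0.604 to 1.08). Copies under other names were not covered. Genes above 0 and under 1 in a library, with at least 10 in the other 3, were fewer than those at 0. They numbered 6 in K562, 3 in THP-1, 3 in the library labelled MOLM13 and 7 in HL60. Transfer to an overlapping gene, lines that differ in their use of a gene, and estimates that failed in 1 library all stay open. A test of line differences on the ribosomal protein genes RPS27A, RPS27 and RPL26 was dropped after its result was seen, since it restates the pattern.

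In the library labelled MOLM13, stem cell and T cell genes were high and granule genes low. RHAG, KRT8 and KRT18 reached 98.2%, 82.7% and 85.6% of their K562 levels, but HBE1 reached 0.105% of its K562 level, which argues against K562 cells or RNA in the library. Of 9 low primary granule genes 2 were listed at 0, which argues against failed estimates as the source of their low levels. A wrong label may account for CD34 at 194 and, unless those estimates failed, for FLT3 and MEIS1 listed at 0, and it cannot be told apart from the biology of the line, since no reference profile of MOLM13 was available. No biological explanation was tested, and the deposited file of this library carries another name than its label, which leaves the question open for every value of the library.

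Footprint signal on lncRNA genes could come from reads of an overlapping protein-coding gene, since 69.7% of the 881 genes with signal shared exons with another gene, against 38.1% of all 14841. The median correlation over the 4 lines was 0.132 for 426 overlapping pairs and 0.189 for 267 pairs of nearest genes, a difference of -0.0575 (-0.20 to 0.0956). This does not decide the question, since each correlation rests on 4 values and reads divided between overlapping genes need not rise together. Of 614 genes with signal and shared exons, 426 entered this comparison. For genes without overlap, the median level was 27.2% of the protein-coding median as the mean of the 4 libraries. It was 30.3%, 26.8%, 29.9% and 21.7% in K562, THP-1, the library labelled MOLM13 and HL60, against 3′ untranslated coverage of 18.2%, 21.3%, 18.0% and 25.1% of coding coverage, but the order depends on how that ratio is taken: medians over genes with coding coverage of at least 10 lay under the lncRNA level in all 4 libraries, and ratios of coverage summed over genes with at least 1 lay over it in all 4. The lncRNA and 3′ untranslated percentages are also unlike measures. The lncRNA level compares different genes, all chosen at a scaled TPM of at least 1 and at least 600 aligned bases. The 3′ untranslated ratio is taken within transcripts that have an exon wholly in that region, with no such floor on it. Signal that is not from translating ribosomes stays open, since the deposited values hold no reading frame.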
